A study of Homo sapiens with 15 samples.

How the data were processed

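Gene expression was measured on 15 Affymetrix high-throughput human genome arrays, 1 per culture of MCF10A cells, a nonmalignant human mammary epithelial line. The groups were sham (n = 3), irradiation alone (IR, n = 4), transforming growth factor beta alone (TGFβ, n = 4) and both treatments (IR+TGFβ, n = 4). The deposited values are log2 probe set levels, which the authors made with RMA in R 2.3.0, per the labels. The sorted values of any pair of arrays differed by at most 0.148 at any rank, as quantile normalisation leaves them, and the values were used as levels with no further scaling. The probe definitions behind the RMA values are not stated in the labels.

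Probe sets were joined to gene symbols through the platform annotation table. Of the probe sets, 19724 had 1 symbol, 568 had several, 1923 had none and 62 were controls, and only those with 1 symbol were used. Each gene was represented by its probe set with the highest mean log2 level over all arrays, which gave 12165 genes. Of these, 4505 had more than 1 probe set. No filter on dim genes was applied. The number of arrays limits the precision: the median standard error of a log2 change was 0.0953 against sham, 0.0825 between treated groups and 0.126 for the interaction.

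The first digit of each array's replicate number was read as its experiment, because each treated group then has 2 arrays per experiment, as the series text describes. All 3 sham arrays carry the digit 2. The 15 arrays were fitted together in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes), with the group and the experiment as terms. Arrays of the same group and experiment counted as independent replicates. The SE and p-values therefore mainly measure the spread between cultures within an experiment, not how far a change repeats over experiments. A difference from sham therefore takes the experiment 1 arrays of the treated groups through an additive experiment term. The 6 contrasts were TGFβ, IR and IR+TGFβ each against sham, IR+TGFβ against TGFβ and against IR, and the interaction, which is the change from IR to IR+TGFβ less the change from sham to TGFβ. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 12165 genes, and the tests were two-sided. All p-values of genes below are adjusted limma values unless called unadjusted.

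The 26 gene lists were written from general knowledge of the field, and some share members (FAP is in the mesenchymal and the fibroblast marker list, CDH3 in the epithelial and the basal list, CDKN1A in the SMAD-induced and the p53 list). Each was tested with camera in limma at its preset inter-gene correlation of 0.01, adjusted over all lists and the 6 contrasts. The same test with an estimated correlation, and fry, were run as alternatives. The lists were mesenchymal, epithelial junction, desmosome and hemidesmosome, TGFβ/SMAD-induced, TGFβ/SMAD-repressed, matrix protease, actin, integrin, p53 target, DNA repair, S phase, G2 and mitosis, interferon response, NF-kB and secreted inflammatory, squamous differentiation, basal mammary, luminal mammary, EGF receptor ligand and ERK feedback, cholesterol synthesis, hypoxia and glycolysis, unfolded protein response, oxidative stress (NRF2), antigen presentation, fibroblast marker, blood and endothelial marker, and ribosomal protein.

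Named genes were chosen by a rule. In each contrast they are the 10 largest rises and 10 largest falls among called genes with the same sign in the fit without the experiment term and in the experiment 2 arrays alone. Where no gene was called, the 3 smallest p-values are given. To these come 12 genes fixed for the comparisons with sham and of IR+TGFβ with TGFβ (CDH1, CDH2, CTNNB1, TJP1, FN1, VIM, SNAI2, TGFBI, ID1, CDKN1A and MDM2, with one more that is not reported here), and up to 4 members with the smallest p of each list described.

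The groups, the model, the lists, the naming rule and most alternatives were set before the data were examined. The alternatives were no experiment term, the experiment 2 arrays alone, the experiment as a random block, the replicate number as a block, only the groups compared in the fit, cyclic loess and median centring between arrays, the brighter part of the genes, the mean of a gene's probe sets, no cross-hybridising (_x_at) probe sets, eBayes with trend and robust options, a log2 change over 0.8, the study's own selection rule, and each array left out in turn. Fits to the experiment 1 arrays alone, and with the IR+TGFβ arrays of experiment 2 only, were added after the data were seen. The pipeline was tested on simulated arrays with normal noise of each gene's own size and known changes: at a true log2 change of 0.5 it recovered 48% of the genes for the interaction and 70% to 92% for the other contrasts, and at 1.0 it recovered 96% to 100%. Between 2.29% and 7.5% of its calls were false. The simulated experiment effect was the same in every group, and the noise was independent between arrays and genes. In the data the effect of irradiation on top of TGFβ differed between the experiments for 265 genes, so these rates need not carry over. Plots were drawn with matplotlib.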

Results

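The data are RMA log2 levels of 12165 genes in MCF10A cells, a nonmalignant human mammary epithelial line. The cells received sham handling, X-rays (IR, 2 Gy at 160 kV, 5 h after plating), TGFβ in the medium (400 pg/ml) or both (IR+TGFβ), and were harvested 8 days after irradiation. The series title places the study at the start of an epithelial to mesenchymal transition, a change in which epithelial cells lose junctions and gain mesenchymal genes. There were 3 sham arrays, all of experiment 2, and 4 arrays in each treated group, 2 from each of the 2 experiments. Levels ran from 4.32 to 15.38 and array medians from 6.35 to 6.44. Arrays are named by group and replicate number, whose first digit is the experiment. Log2 changes are fitted with the experiment as a term, so those against sham can depart from the difference of the unadjusted group means, which are given with their SD. That term is additive. For genes whose treatment effect differed between the experiments it does not hold, and the SE of their changes against sham does not fully cover this.

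**Figure D1:**
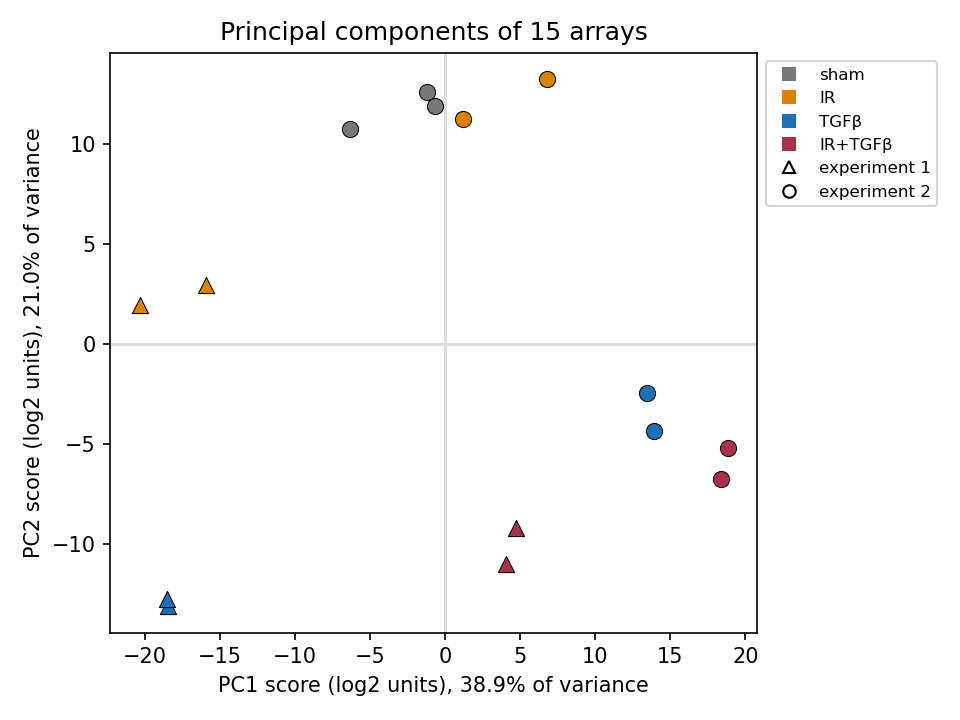
Scores of the 15 arrays on the first and second principal components (log2 units), coloured by group and shaped by experiment. The first component holds 38.9% of the variance and the second, on which all 8 arrays with TGFβ lie below 0 and the 7 without it above 0, holds 21%.

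TGFβ against sham asks what the cytokine changed without irradiation. POSTN, which encodes the matrix protein periostin, had a mean of 5.11 ± 0.23 (SD, n = 3) in sham and of 10.86 ± 0.29 (SD, n = 4) after TGFβ, and its fitted log2 change was 5.93 ± 0.12 (SE) with an adjusted p of 2.69e-14. In sham its level stood at percentile 10.6 of all genes, among the mean levels of the 13 blood and endothelial markers (4.78 to 5.90), so array background limits the size of its changes and their SE does not cover this. The sham levels of TNFAIP6 (5.56), SAMSN1 (5.67) and HSD17B2 (5.89) lay in that range too, and the same holds for their changes. FN1, fibronectin, rose by 2.84 ± 0.09 in the fit with an adjusted p of 1.17e-11, and its means were 10.73 ± 0.11 (SD, n = 3) in sham and 13.34 ± 0.18 (SD, n = 4) after TGFβ. E-cadherin, CDH1, the adhesion protein of epithelial junctions, fell by 0.74 ± 0.10 (SE) in the fit with an adjusted p of 0.00032, and its means were 11.03 ± 0.06 (SD, n = 3) and 10.24 ± 0.11 (SD, n = 4), with 4 of 4 arrays below every sham array. N-cadherin, CDH2, rose by 0.59 ± 0.07 with an adjusted p of 0.00022, and TGFBI, a secreted TGFβ target, by 0.66 ± 0.08 with an adjusted p of 0.000162.

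Other large rises after TGFβ were in the chemotactic receptor gene FPR1 (2.33), the chemokine gene CXCL1 (1.94), WNT5A (1.75), which encodes a secreted Wnt ligand, the hyaluronan-binding TNFAIP6 (2.01), the steroid dehydrogenase HSD17B2 (1.89) and DLC1 (1.67). The basal keratin KRT15 fell by 3.00 ± 0.46 (SE), though its 4 TGFβ arrays spread widely (9.82 ± 1.66, SD) against 12.04 ± 0.53 (SD, n = 3) in sham. The additive experiment term does not hold for KRT15, nor for VAV3, PTX3, ID1 and PERP below. Their change from TGFβ to IR+TGFβ differed between the experiments. For KRT15 it was -2.40 in experiment 1 and -0.09 in experiment 2. Carbonic anhydrase CA2 (-2.0), the plasminogen activator PLAT (-1.88), the ion transport regulator FXYD3 (-1.87), the exchange factor VAV3 (-1.70), the receptor FGFR3 (-1.60), the sulfotransferase SULT1E1 (-1.52), TMT1A (-1.38), BBOX1 (-1.36) and ST6GALNAC2 (-1.30) also fell. SAMSN1 (1.91, adjusted p = 0.0157) and PTX3 (1.81, adjusted p = 0.0373) were called, but not without TGFβ 22 (adjusted p = 0.0767 and 0.153) or TGFβ 23 (0.0769 and 0.184). They were also lost without sham 21 (0.0534 and 0.0943), sham 22 (0.0549 and 0.128) or sham 23 (0.0537 and 0.0907), and PTX3 without IR 21 (0.0512) or IR 22 (0.0519). Of the fixed genes, CTNNB1 (-0.18, adjusted p = 0.479), TJP1 (0.08, 0.789), VIM (0.02, 0.943), SNAI2 (0.18, 0.583), ID1 (-0.17, 0.868), CDKN1A (-0.02, 0.930) and MDM2 (-0.30, 0.370) were not called.

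**Figure D2:**
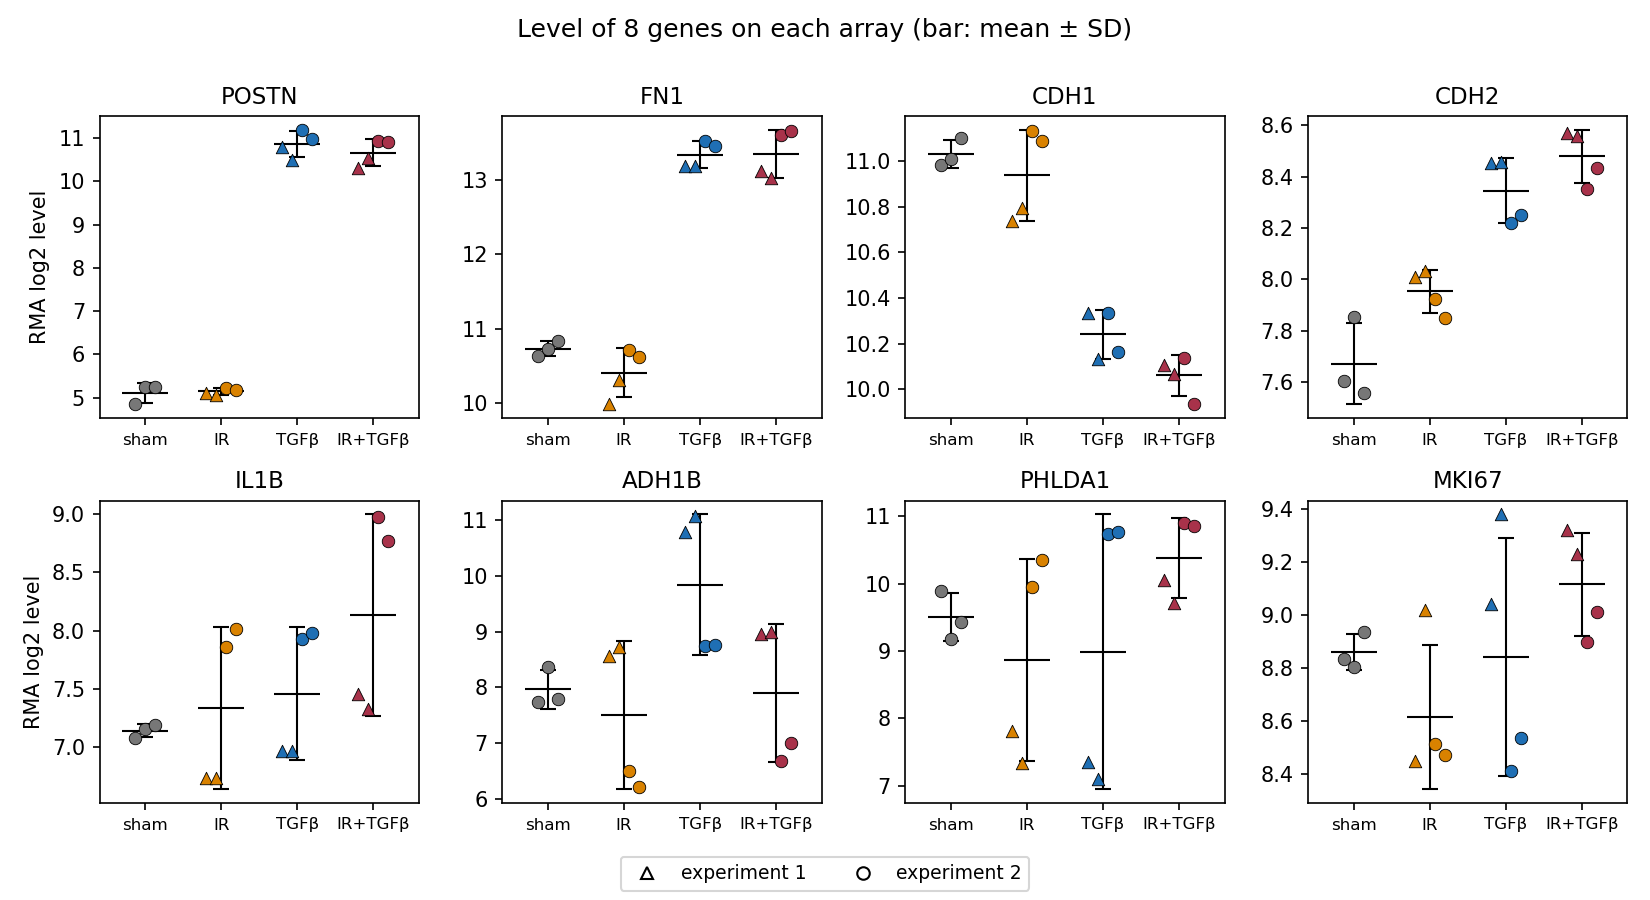
RMA log2 level of 8 genes on each of the 15 arrays, by group, with the experiment as the marker shape and bars for the mean ± SD. POSTN lies between 10.3 and 11.2 on the 8 arrays with TGFβ and between 4.84 and 5.25 on the other 7, while ADH1B and PHLDA1 part by experiment within the treated groups.

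Among the lists, the TGFβ/SMAD-induced genes rose after TGFβ: of 28 measured, 8 rose and 0 fell (11 rose and 1 fell adjusted over the list alone), median 0.19, camera adjusted p = 6.33e-11, led by the collagens COL4A2 (1.47) and COL4A1 (1.14) and by IGFBP7 (1.51). Of 27 mesenchymal genes 9 rose and 0 fell (9 and 1 adjusted over the list alone; median 0.12, adjusted p = 3.86e-09), with POSTN, FN1, CDH2 and the fibroblast protease FAP (1.57) in front. The fibroblast marker list, which shares FAP, had 2 of 12 members up, FAP and DCN (0.85), with a median of 0.04 and an adjusted p of 0.03, lost without sham 21 (0.0591) or sham 23 (0.0767). Of 21 epithelial junction genes 7 fell and 0 rose (11 fell adjusted over the list alone; median -0.28, adjusted p = 2.22e-07), among them EPCAM (-1.24), CDH3 (-0.64) and LSR (-0.49). Of 17 desmosome and hemidesmosome genes 7 fell and 0 rose (11 fell adjusted over the list alone; median -0.33, adjusted p = 2.35e-08), among them DSG3 (-0.74), PERP (-0.73), PPL (-0.68) and plakoglobin JUP (-0.62). The NF-kB and secreted inflammatory list had 6 of 23 up and 0 down (9 up adjusted over the list alone; median 0.21, adjusted p = 6.08e-06; median 0.0012 without the experiment term), with CXCL1, CXCL2 (1.11), CXCL3 (0.96) and the cytokine IL1B (0.93). These 5 lists other than the fibroblast one held with an estimated correlation (adjusted p = 0.000953, 0.00141, 0.00257, 0.0474 and 0.0423).

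The other lists that moved after TGFβ were lost with an estimated correlation. Basal mammary genes (14 measured) had 1 up, the peptidase MME (1.06), and 6 down, among them TRIM29 (-1.0) and KRT5 (-0.62), or 3 and 9 adjusted over the list alone, with a median of -0.43 and an adjusted p of 0.000102 (adjusted p = 0.126 with an estimated correlation). Of 25 G2 and mitosis genes 0 rose and 2 fell, CDKN3 (-0.49) and PTTG1 (-0.48), or 3 adjusted over the list alone, median -0.26, adjusted p = 3.75e-06 (adjusted p = 0.446 with an estimated correlation). That median was -0.43 in experiment 2 alone and -0.05 without the experiment term. PTTG1 was not called without any 1 of the sham arrays 21 (0.0711), 22 (0.128) and 23 (0.0934) or of TGFβ 22 (0.141) and 23 (0.172), nor CDKN3 without TGFβ 22 (0.0503). Of 20 matrix protease genes only SERPINE2 (1.32) rose (4 adjusted over the list alone; median 0.13, adjusted p = 0.000199; adjusted p = 0.0754 with an estimated correlation). Of 23 p53 targets 1 rose and 6 fell (1 and 7 adjusted over the list alone), among them SFN (-0.30), with a median of -0.16 and an adjusted p of 0.00107 (adjusted p = 0.19 with an estimated correlation). Squamous genes (1 of 23 down, 4 adjusted over the list alone; median -0.10, adjusted p = 0.0219; adjusted p = 0.338 with an estimated correlation) were lost without sham 22 (0.0877) or TGFβ 12 (0.0561). The oxidative stress list (16 measured; 1 up, ferritin FTL at 0.54, and 2 down, AKR1C1 at -0.62 and AKR1C2 at -0.56, or 1 and 4 adjusted over the list alone; median -0.13, adjusted p = 0.0426; adjusted p = 0.256 with an estimated correlation) was lost under cyclic loess (0.0706). It was also lost without IR 12 (0.0523), IR+TGFβ 13 (0.0526), IR+TGFβ 21 (0.0656), sham 21 (0.0704), sham 22 (0.0784), TGFβ 12 (0.0526) or TGFβ 23 (0.119). Unfolded protein genes (0.154) were called without sham 21 (0.0354). Without the experiment term the medians of the TGFβ/SMAD-induced, basal, matrix protease and p53 lists were 0.10, -0.28, 0.04 and -0.05, and in experiment 2 alone those of the squamous and fibroblast lists were -0.06 and 0.07.

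Over all genes TGFβ raised 157 and lowered 219, a total of 376, and 1791 genes had an unadjusted p under 0.05. In the experiment 2 arrays alone 618 genes were called and 326 of the 376 were among them. Without the experiment term 151 were called, 148 of them shared, and KRT15, TNFAIP6, HSD17B2 and DLC1 were then not called (adjusted p = 0.174, 0.474, 0.237 and 0.493). The total was 233 without sham 22, 232 without sham 23, 242 without TGFβ 22 and 202 without TGFβ 23.

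IR against sham asks what a single 2 Gy dose left behind after 8 days. By limma 3 genes were called and 795 had an unadjusted p under 0.05. The cytokine gene IL1B rose by 0.81 ± 0.10 (SE, adjusted p = 0.00473), the alcohol dehydrogenase ADH1B fell by 1.57 ± 0.14 (adjusted p = 0.000121), and PALMD, which encodes the cytosolic protein palmdelphin, fell by 0.64 ± 0.09 (adjusted p = 0.0185) with 4 of 4 arrays below every sham array. The experiments differed in the level of IL1B and ADH1B, so their IR means over both experiments (7.34 ± 0.70 and 7.50 ± 1.33, SD, n = 4) lay close to sham (7.14 ± 0.06 and 7.97 ± 0.35, SD, n = 3). In experiment 2 alone, where sham and IR meet directly, the changes were 0.79 for IL1B, -1.61 for ADH1B and -0.66 for PALMD. IL1B was not called without IR 22 (adjusted p = 0.0544) or sham 21 (0.0582), nor PALMD without IR 22 (0.102), sham 21 (0.0877), sham 22 (0.0831) or sham 23 (0.119). Without IR 21, 9 genes were called, and 1 without IR 22 or sham 21. Without the experiment term 0 genes were called by limma; ADH1B then stood at -0.47 and IL1B at 0.19.

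The fixed genes were not called after IR. CDH1 differed by -0.04 (adjusted p = 0.976, 95% interval -0.25 to 0.17), CDH2 by 0.19 (0.670), FN1 by -0.10 (95% interval -0.29 to 0.10), and the p53 targets CDKN1A by 0.16 (0.739) and MDM2 by 0.36 ± 0.15 (0.690).

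Of 25 G2 and mitosis genes 0 were called over all genes and 18 fell adjusted over the list alone, with a median of -0.39 and a camera adjusted p of 8.47e-23 (adjusted p = 0.1 with an estimated correlation). Cyclin B2, CCNB2 (-0.50), BIRC5 (-0.47), TOP2A (-0.57) and BUB1B (-0.39) had its smallest p-values. Its median was -0.24 in experiment 2 alone and -0.23 without the experiment term. The 24 S phase genes had 0 called and 0 adjusted over the list alone, with a median of -0.19 (adjusted p = 7.92e-08; adjusted p = 0.151 with an estimated correlation), -0.11 in experiment 2 alone and 0.05 without the experiment term. The NF-kB list rose, with 1 of 23 called and 8 adjusted over the list alone (median 0.18, adjusted p = 3.13e-10, and 0.00793 with an estimated correlation), led by IL1B, CXCL3 (0.66), CXCL2 (0.63) and CXCL1 (0.78). Its median was 0.16 in experiment 2 alone and 0.05 without the experiment term. The 28 TGFβ/SMAD-induced genes shifted up by a median of 0.11 with 0 called either way (adjusted p = 0.000102, and 0.00942 with an estimated correlation). Their median was 0.05 in experiment 2 alone and 0.03 without the experiment term. Desmosome genes had 0 of 17 called and 3 down adjusted over the list alone, DSP (-0.34), PPL (-0.37) and PERP (-0.35), with a median of -0.10 and an adjusted p of 0.00109 (adjusted p = 0.246 with an estimated correlation), lost without IR 22 (0.0702). The matrix protease list (adjusted p = 0.0632) was called without IR 22 (0.036), IR+TGFβ 23 (0.0341) or sham 21 (0.0409). The 16 actin genes (0 called, 1 up adjusted over the list alone, LIMA1 at 0.56, called over all genes without IR+TGFβ 13, 0.0387) had a median of 0.07 and an adjusted p of 0.00123 (adjusted p = 0.215 with an estimated correlation). DNA repair genes (0 of 22 called, 0 adjusted over the list alone, median -0.08, adjusted p = 0.037; adjusted p = 0.246 with an estimated correlation) were lost without IR 11 (0.103), IR 22 (0.122), sham 21 (0.133), sham 23 (0.0638) or TGFβ 22 (0.0638). Basal genes (0 of 14 called, KRT14 at -0.42 down adjusted over the list alone and called over all genes without IR 21, 0.0458, median -0.09, adjusted p = 0.0291; adjusted p = 0.367 with an estimated correlation) were lost without IR 12 (0.0683), IR 22 (0.122), sham 22 (0.194), sham 23 (0.11) or TGFβ 12 (0.0513), and their median turned to 0.06 without the experiment term, where those of the actin and DNA repair lists were 0.02 and -0.0022.

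**Figure D3:**
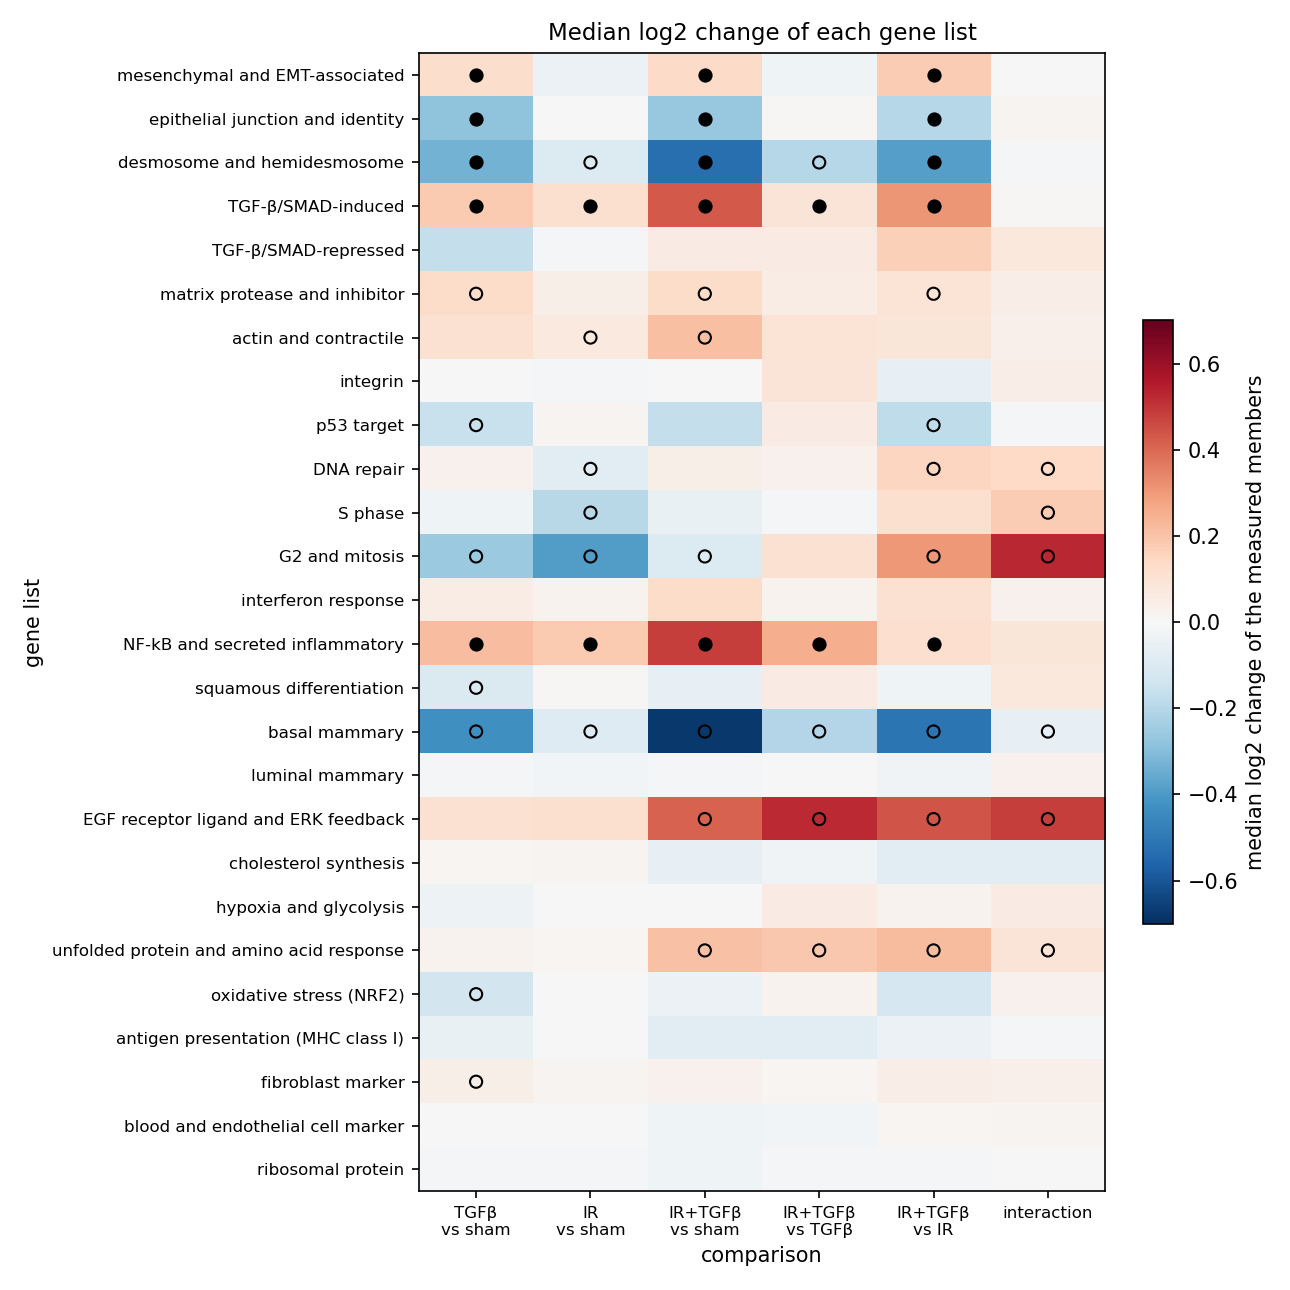
Median log2 change of the measured members of each of the 26 gene lists in the 6 comparisons, with the colour scale ending at 0.7 either way. Open circles mark a camera adjusted p under 0.05, and filled circles lists that also hold with an estimated correlation, such as the TGFβ/SMAD-induced and NF-kB lists in all 5 pairwise comparisons.

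IR+TGFβ against sham asks what both treatments changed together. Of all genes 836 rose and 808 fell, a total of 1644, with 3171 at an unadjusted p under 0.05. POSTN (5.73 ± 0.12), FN1 (2.85), PTX3 (3.41), SAMSN1 (3.04), CXCL8 (2.92), CXCL1 (2.80), HSD17B2 (2.69), the growth factor binding protein IGFBP3 (2.65), DLC1 (2.61) and TNFAIP6 (2.43) rose most by the fitted values, which background limits for POSTN, SAMSN1, HSD17B2 and TNFAIP6. Of the 8 other CXCL8-annotated probe sets 4 had the same sign. KRT15 fell by 4.24 ± 0.46 (SE) in the fit, and its unadjusted means were 12.04 ± 0.53 (SD, n = 3) in sham and 8.57 ± 0.33 (SD, n = 4). VAV3 (-2.74), TMT1A (-2.67), FGFR3 (-2.66), FXYD3 (-2.26), PLAT (-2.26), the selenium carrier SELENOP (-2.25), SULT1E1 (-2.23), CA2 (-1.85) and BBOX1 (-1.67) fell too. The additive experiment term does not hold for PTX3, CXCL8, IGFBP3, KRT15, VAV3 and ID1. Their change from TGFβ to IR+TGFβ differed between the experiments by the test described below. CDH1 fell by 0.92 ± 0.10 (adjusted p = 1.5e-05), CDH2 rose by 0.72 ± 0.07 (adjusted p = 1.18e-05) and TGFBI by 0.45 ± 0.08 (adjusted p = 0.00171). VIM (-0.01, adjusted p = 0.978), SNAI2 (0.20), CTNNB1 (-0.16), CDKN1A (0.09) and MDM2 (-0.17) were not called. ID1 (0.82, adjusted p = 0.0837) was called without IR+TGFβ 21 (0.0332) or IR+TGFβ 23 (0.0341), and TJP1 (0.24, 0.104) was called without IR+TGFβ 13 (0.00592). Without sham 22 the total was 1018. In experiment 2 alone 1097 of the 1644 were called, and without the experiment term 447.

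By list, 15 of 28 TGFβ/SMAD-induced genes rose and 1 fell (17 and 1 adjusted over the list alone; median 0.43, adjusted p = 6.33e-11), with IGFBP7 (1.99), COL4A2 (1.46) and thrombospondin THBS1 (1.0). Of 27 mesenchymal genes 9 rose and 2 fell, the same adjusted over the list alone (median 0.13, adjusted p = 9.46e-05), with FAP at 2.17. Of 21 epithelial junction genes 9 fell and 0 rose (10 and 1 adjusted over the list alone; median -0.27, adjusted p = 2.57e-05), with EPCAM at -1.28. Of 17 desmosome genes 10 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.53, adjusted p = 1.38e-08), with PPL (-1.34), PERP (-1.14), desmoplakin DSP (-0.96) and JUP (-0.85). Of 23 NF-kB genes 12 rose and 0 fell, the same adjusted over the list alone (median 0.49, adjusted p = 1.31e-09), with CXCL2 (2.16), CXCL3 (1.83) and IL1B (1.60). These 5 lists held with an estimated correlation (adjusted p = 0.000953, 0.00942, 0.00793, 0.0455 and 0.00863). The others were lost with it. Basal genes had 8 of 14 down and 2 up (9 and 2 adjusted over the list alone; median -0.67, adjusted p = 2.21e-05; adjusted p = 0.101 with an estimated correlation), with TRIM29 (-1.50), KRT5 (-1.14) and KRT14 (-0.93). The EGF receptor ligand and ERK feedback list had 9 of 18 up and 0 down (10 adjusted over the list alone; median 0.41, adjusted p = 3.3e-05; adjusted p = 0.44 with an estimated correlation), with PHLDA1 (2.05) and IER3 (1.63). The additive experiment term does not hold for either gene, nor for PERP. On the arrays of experiment 2 PHLDA1 stood at 10.89 and 10.86 after IR+TGFβ and at 9.90, 9.19 and 9.43 in sham. The unfolded protein list had 6 of 19 up and 0 down (8 adjusted over the list alone; median 0.21, adjusted p = 0.00013; adjusted p = 0.338 with an estimated correlation), with SDF2L1 (0.62) and DDIT3 (0.67). Of 20 matrix protease genes 7 rose and 0 fell, the same adjusted over the list alone (median 0.13, adjusted p = 0.000734; adjusted p = 0.101 with an estimated correlation), with SERPINE2 (1.76) and TIMP1 (0.37). Of 16 actin genes 4 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.21, adjusted p = 0.0174; adjusted p = 0.338 with an estimated correlation), with TAGLN at 0.79 and TPM1 at -0.46, lost without IR+TGFβ 21 (0.0505) or 23 (0.0871). The G2 and mitosis list (4 of 25 down and 0 up, also adjusted over the list alone; median -0.09, adjusted p = 0.0493; adjusted p = 0.746 with an estimated correlation) was lost without IR+TGFβ 13 (0.0805), IR+TGFβ 21 (0.221), sham 21 (0.206) or any 1 of the TGFβ arrays 12 (0.0792), 13 (0.0895), 22 (0.0851) and 23 (0.0829), and its median was 0.02 without the experiment term. Without that term the medians of the NF-kB, ERK feedback, mesenchymal and actin lists were 0.18, 0.13, 0.08 and 0.13, and in experiment 2 alone those of the ERK feedback and mesenchymal lists were 0.25 and 0.07.

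IR+TGFβ against TGFβ asks what the earlier irradiation added in cells that all received TGFβ. The genes INHBA (1.01 ± 0.13, adjusted p = 0.000938), which encodes an activin subunit, IL1B (0.68 ± 0.09, 0.00113), CXCL3 (0.88 ± 0.13, 0.00248) and the prostaglandin synthase PTGS2 (0.88 ± 0.14, 0.00381) rose, with the same sign in each experiment. INHBA changed by 0.75 in experiment 1 and 1.27 in experiment 2, IL1B by 0.43 and 0.92, CXCL3 by 0.77 and 0.99, and PTGS2 by 0.56 and 1.21. ADH1B fell by 1.94 ± 0.12 (adjusted p = 7.24e-07), with -1.96 in experiment 1 and -1.92 in experiment 2. These fixed genes were not called: CDH1 differed by -0.18 (adjusted p = 0.290), CDH2 by 0.13 (0.304), FN1 by 0.01, TGFBI by -0.21 (0.120), CDKN1A by 0.11 and MDM2 by 0.13.

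Other genes had a larger estimate in experiment 1 than in experiment 2. CXCL8 rose by 1.53 (2.48 in experiment 1, 0.58 in experiment 2), CXCL2 by 1.05 (1.43 and 0.68), AMIGO2 by 1.04 (1.66 and 0.42) and IL1A by 1.04 (1.67 and 0.40). TMT1A changed by -1.29 (-1.80 and -0.78), FGFR3 by -1.06 (-1.33 and -0.79). In experiments 1 and 2 the other large rises were CCL20 (2.12 and 0.34), TRIB1 (2.08 and 0.18), IER3 (2.00 and 0.42) and ATF3 (1.96 and 0.29). The other large falls were CYP4B1 (-1.91 and -0.07), VAV3 (-1.86 and -0.21), SELENOP (-1.61 and -0.40), SELENBP1 (-1.50 and -0.64), APOE (-1.48 and -0.33), EIF2S3 (-1.41 and -0.97) and F2R (-1.16 and -0.69). The difference between the experiments was itself called for CXCL8, AMIGO2 and IL1A, and not for CXCL2 (adjusted p = 0.102), TMT1A (0.137) or FGFR3 (0.389). The calls of 3 more genes were lost without single arrays. PTX3 (1.60; 3.01 and 0.19), PHLDA1 (1.39; 2.65 and 0.13) and ID1 (0.99, adjusted p = 0.0442; 1.90 and 0.08) had adjusted p-values of 0.106, 0.124 and 0.133 without IR+TGFβ 11 and of 0.115, 0.131 and 0.141 without IR+TGFβ 13. Without TGFβ 12 they were 0.112, 0.131 and 0.143, and without TGFβ 13 0.138, 0.158 and 0.17. PHLDA1 was also lost without IR 11 (0.0513), IR 21 (0.0532) or sham 23 (0.0544), and ID1 without IR 11 (0.0579), IR 12 (0.0507), IR 21 (0.0593), IR 22 (0.0519), sham 21 (0.0559), sham 22 (0.0518), sham 23 (0.0605) or TGFβ 22 (0.0501). TJP1 was called without IR+TGFβ 13 (0.0411).

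Over all genes 299 rose and 136 fell in that comparison, a total of 435, with 2122 at an unadjusted p under 0.05. Cyclic loess gave 254 up and 203 down. All 435 had the same sign in both experiments, which a call on the average of the experiments favours, with a median size of 0.48 in experiment 1 and 0.30 in experiment 2, and 16 were called in both. Experiment 1 alone called 680 genes and experiment 2 alone 18. Without the experiment term, which leaves these log2 changes as they are and widens their spread, 0 were called by limma. The total was 210 without IR+TGFβ 11, 161 without IR+TGFβ 13, 154 without TGFβ 12 and 96 without TGFβ 13.

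By list, 10 of 23 NF-kB genes rose and 0 fell with irradiation on top of TGFβ (12 adjusted over the list alone; median 0.25, adjusted p = 5.34e-10, and 0.00793 with an estimated correlation), with medians of 0.43 in experiment 1 and 0.27 in experiment 2. Of 28 TGFβ/SMAD-induced genes 6 rose and 0 fell (10 and 1 adjusted over the list alone; median 0.09, adjusted p = 0.00696, and 0.0485 with an estimated correlation). In experiments 1 and 2 IGFBP3 changed by 1.71 and 0.31, BAMBI by 1.49 and 0.12, and BHLHE40 by 0.91 and 0.23. INHBA had its larger estimate in experiment 2 (0.75 and 1.27). These were the list's members with the smallest p, and the difference between the experiments was called for IGFBP3 and BAMBI. Of 18 EGF receptor ligand and ERK feedback genes 3 rose and 0 fell (14 adjusted over the list alone; median 0.52, adjusted p = 1.56e-09; adjusted p = 0.247 with an estimated correlation), with medians of 1.02 in experiment 1 and 0.00025 in experiment 2, where the list was not called. Its member IER3 (1.21) was called, but not without TGFβ 13 (0.0503). The unfolded protein list had 2 of 19 up, 0 down (5 adjusted over the list alone; median 0.19, adjusted p = 5.24e-05; adjusted p = 0.312 with an estimated correlation), with medians of 0.24 and 0.04 in experiments 1 and 2, and SDF2L1 rose by 0.48. Desmosome genes had 3 of 17 down and 1 up (5 and 1 adjusted over the list alone; median -0.20, adjusted p = 0.000254; adjusted p = 0.19 with an estimated correlation). Among them PPL fell by 0.66 and LAMB3 rose by 0.45, and the list had medians of -0.33 in experiment 1 and -0.09 in experiment 2. Basal genes had 3 of 14 down and 0 up (5 adjusted over the list alone; median -0.20, adjusted p = 8.88e-05; adjusted p = 0.124 with an estimated correlation), with KRT5 (-0.52) and TRIM29 (-0.50), and medians of -0.40 and -0.09 in experiments 1 and 2. Neither list was called in experiment 2 (0.123 and 0.0685). The mesenchymal (adjusted p = 0.789) and epithelial junction (0.608) lists were not called. G2 and mitosis genes (median 0.11, 0.0885) were called without IR 11 (0.0485), IR+TGFβ 13 (0.037), IR+TGFβ 21 (0.0446), TGFβ 12 (0.00351) or TGFβ 13 (0.000517). Actin genes (0.0632) were called without IR+TGFβ 13 (0.00171), TGFβ 12 (0.0384) or TGFβ 13 (0.00939).

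IR+TGFβ against IR gives the TGFβ effect in irradiated cells, and its group means come from arrays other than those of TGFβ against sham. The contrasts are not fully separate. The experiment term in TGFβ against sham was also estimated from the IR and IR+TGFβ arrays, and both contrasts use the same estimate of the spread. POSTN rose by 5.52 ± 0.11, FN1 by 2.95 ± 0.08, PTX3 by 2.96, SAMSN1 by 2.69, IGFBP3 by 2.37, CXCL8 by 2.17, DLC1 by 2.05, CXCL1 by 2.02, HSD17B2 by 1.99 and the adhesion gene CADM3 by 1.71. KRT15 (-3.62), FXYD3 (-2.12), SULT1E1 (-1.98), VAV3 (-1.92), FGFR3 (-1.91), TMT1A (-1.80), PLAT (-1.65), CA2 (-1.51), SELENOP (-1.44) and TRIM29 (-1.29) fell most, and CDH1 (-0.88) and EPCAM (-1.13) fell too. In all 636 genes rose and 589 fell, a total of 1225, with 2784 at an unadjusted p under 0.05. All 1225 had the same sign in both experiments, which such a call favours, and 328 were called in both. The total was 796 without IR 21, 540 in experiment 2 alone and 405 without the experiment term. Across genes the changes of this contrast and of TGFβ against sham correlated with a Pearson coefficient of 0.738 and a Spearman coefficient of 0.505, where genes are not independent replicates. Of the genes called in both, 311 went the same way (18.8 by chance), 178 of them down (10.6 by chance), and 1 went opposite ways. Without the experiment term these coefficients were 0.496 and 0.288, and 104 genes called in both went the same way (2.52 by chance). With only the compared groups in each fit, so that the fits share no arrays, they were 0.750 and 0.517. In those fits 432 genes called in both went the same way (26.7 by chance). For the IR effect, from IR against sham and IR+TGFβ against TGFβ, the Pearson coefficient was 0.438 with the experiment term, 0.234 in experiment 2 alone and -0.138 without the term.

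The lists of that comparison that held with an estimated correlation were the same 5 as for TGFβ against sham. Of 28 TGFβ/SMAD-induced genes 14 rose and 1 fell (17 and 1 adjusted over the list alone; median 0.31, adjusted p = 8.51e-10, and 0.00113 with an estimated correlation). Of 27 mesenchymal genes 10 rose and 0 fell (11 adjusted over the list alone; median 0.18, adjusted p = 3.38e-08, and 0.00194), with FAP (1.63) and the fibronectin receptor ITGA5 (0.63). Of 21 epithelial junction genes 9 fell and 0 rose (10 adjusted over the list alone; median -0.20, adjusted p = 7.99e-08, and 0.0023). Of 17 desmosome genes 10 fell and 1 rose, the same adjusted over the list alone (median -0.39, adjusted p = 9.03e-09, and 0.0447). Of 23 NF-kB genes 11 rose and 0 fell, the same adjusted over the list alone (median 0.12, adjusted p = 3.1e-06, and 0.0377). Lost with an estimated correlation were basal genes (2 up and 8 down of 14, 3 and 9 adjusted over the list alone, median -0.51, adjusted p = 9.72e-06; adjusted p = 0.0955 with an estimated correlation), ERK feedback genes (6 of 18 up, 12 adjusted over the list alone, median 0.44, 9.03e-07; adjusted p = 0.341 with an estimated correlation) and unfolded protein genes (4 of 19 up, 10 adjusted over the list alone, median 0.22, 9.72e-06; adjusted p = 0.26 with an estimated correlation). So were matrix protease genes (6 of 20 up, also adjusted over the list alone, median 0.10, 0.00183; adjusted p = 0.124 with an estimated correlation) and p53 targets (2 up and 7 down of 23, 2 and 10 adjusted over the list alone, median -0.18, 0.00527; adjusted p = 0.254 with an estimated correlation), with CCNG1 (-0.48) and ZMAT3 (-0.50). The ERK feedback medians were 0.81 in experiment 1 and 0.21 in experiment 2. G2 and mitosis genes had 5 of 25 up and 1 down (10 and 1 adjusted over the list alone; median 0.31, adjusted p = 4.03e-05; adjusted p = 0.499 with an estimated correlation), among them MKI67 (0.50) and BUB1B (0.39), with medians of 0.48 in experiment 1 and 0.05 in experiment 2. DNA repair genes (2 of 22 up, 4 adjusted over the list alone, median 0.15, 0.0196; adjusted p = 0.19 with an estimated correlation) were lost without IR 11 (0.0684) or IR+TGFβ 23 (0.0525). The S phase list (0.166) was called without IR+TGFβ 13 (0.0281), and the oxidative stress list (0.0668) without IR+TGFβ 23 (0.0306).

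The interaction asks whether TGFβ changed irradiated and unirradiated cells by different amounts. By limma 0 genes were called, and 637 had an unadjusted p under 0.05. The smallest adjusted p-values were those of the immediate early gene EGR1 (0.96 ± 0.15, adjusted p = 0.111), of BMAL2 (0.75, 0.651) and of COL6A1 (-0.70, 0.651). Whether the other probe set of EGR1 had the same sign was not computed for the interaction. EGR1 was called without IR 22 (0.0462) or sham 22 (0.0164), and with the trend and robust options (0.00581). As a list, the 25 G2 and mitosis genes had a median interaction of 0.53 (0 called over all genes, 14 up adjusted over the list alone, camera adjusted p = 3.63e-21; adjusted p = 0.109 with an estimated correlation), and 0.41 in experiment 2 alone. ERK feedback genes had a median of 0.48 (1 up adjusted over the list alone, adjusted p = 7.73e-08; adjusted p = 0.306 with an estimated correlation) but of -0.13 in experiment 2 alone, where the list was not called. S phase genes (0.18, adjusted p = 0.00128; adjusted p = 0.384 with an estimated correlation) were lost without TGFβ 23 (0.0835) and had a median of -0.02 without the experiment term, unfolded protein genes had 0.09 (1 up adjusted over the list alone, adjusted p = 0.000214; adjusted p = 0.348 with an estimated correlation), and DNA repair genes (0.14, adjusted p = 0.0219; adjusted p = 0.194 with an estimated correlation) were lost without IR 22 (0.0613) or TGFβ 22 (0.209). Basal genes (-0.06, adjusted p = 0.0299; adjusted p = 0.367 with an estimated correlation) were lost without IR 21 (0.246), sham 21 (0.223), IR+TGFβ 11 (0.106), IR+TGFβ 13 (0.0805), TGFβ 12 (0.0709) or TGFβ 13 (0.0703). The S phase, DNA repair and basal lists had 0 members called over all genes or adjusted over the list alone. In experiment 2 alone the medians of the unfolded protein and basal lists were 0.03 and -0.02. Without the experiment term the medians of the G2, ERK feedback, unfolded protein, DNA repair and basal lists were 0.32, 0.85, 0.16, 0.04 and -0.33. The NF-kB (adjusted p = 0.166) and squamous (0.334) lists were called without TGFβ 23 (0.0291 and 0.048).

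The remaining 9 lists were not called in any of the 6 contrasts with all arrays. After IR+TGFβ against sham, the interferon response list had 8 of 25 up and 2 down (median 0.13, adjusted p = 0.0787) and was called without IR+TGFβ 13 (0.0188). Without that array it was also called in IR+TGFβ against IR (0.0108) and against TGFβ (0.0395), and in TGFβ against sham it was called without TGFβ 22 (0.0275) or TGFβ 23 (0.0335). In the same contrast luminal mammary genes had 1 of 16 up and 3 down (median -0.01, adjusted p = 0.485), integrins 1 of 11 up and 1 down (3 and 1 adjusted over the list alone; 0.00067, 0.621), TGFβ/SMAD-repressed genes 0 of 5 up and 1 down (1 and 1 adjusted over the list alone; 0.06, 0.957) and hypoxia and glycolysis genes 2 of 17 up and 1 down (0.0013, 0.678). Cholesterol synthesis genes had 1 of 13 up (0 adjusted over the list alone; median -0.06, adjusted p = 0.684), antigen presentation genes 1 of 13 up (-0.08, 0.433), and the 13 blood and endothelial markers (-0.03, 0.752) and 22 ribosomal protein genes (-0.03, 0.357) had 0 called. The counts of the other lists of this paragraph were the same adjusted over the list alone.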

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

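All tests of causes in this part were chosen only after the result was seen. The counts over other splits of the arrays were planned before the data were examined, except those over splits that spread the experiments as the real one does.

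The effect of irradiation on top of TGFβ differed between the experiments. By a test of the difference itself (limma, both experiments in 1 fit), 265 genes changed by different amounts, with experiment 2 minus experiment 1 above 0 for 106 and below 0 for 159. Within that fit 1059 genes were called between IR+TGFβ and TGFβ in experiment 1 and 33 in experiment 2, and the changes of the experiments correlated across genes with r = 0.20. Genes whose difference (experiment 2 minus experiment 1) passed the test were PTX3 (-2.818), PHLDA1 (-2.527), TRIB1 (-1.9), CXCL8 (-1.895), CCL20 (-1.784), ATF3 (-1.671), IER3 (-1.578), IL1A (-1.268), AMIGO2 (-1.24), ID1 (-1.822), IGFBP3 (-1.399) and BAMBI (-1.363), whose rise was larger in experiment 1. VAV3 (1.651), CYP4B1 (1.844), APOE (1.151), KRT15 (2.311) and PERP (0.539) fell further in experiment 1. For IR+TGFβ against IR the effect differed for 21 genes, PTX3 (-1.944) among those named.

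A wrong experiment number on the IR+TGFβ arrays of experiment 1 would put them level with those of experiment 2. Along the direction in which the IR and TGFβ arrays of the experiments differ, the IR+TGFβ arrays stood apart by 0.4352 of that difference or more (0.435 to 0.519). This share, well above 0, argues against it. The shares were 0.660 to 0.975 for IR and 1.18 to 1.19 for TGFβ. The direction and its 2206 genes came from those same arrays, so their shares centre on 1 by construction and are no yardstick. RNA degradation stays open: with the 3' to 5' signal of the actin and GAPDH controls as covariates 200 of the 265 genes stayed called, but 0 genes followed either covariate by limma at an adjusted p under 0.05, so this correction decides nothing. A candidate explanation that also stays open is a different state of growth factor signalling in the dishes of experiment 1, since the ERK feedback list differed by -1.029 between the experiments' effects. That value was seen before the explanation was formed and no label records the state of the dishes, so it cannot be told apart from other differences between the experiments. No biological explanation was tested.

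The G2 and mitosis list had a positive interaction, a median of 0.53, so TGFβ and irradiation together lowered it less than the sum of their separate effects. No single sham array sets it, as the lowest median without 1 of them was 0.4526, and over all arrays left out in turn it ran from 0.450 to 0.632. The experiment 2 arrays alone, which need no experiment term, gave 0.4121 with 25 of 25 members above 0, which argues against a leak of the difference between experiments. Under cyclic loess the median was 0.50. A less than additive response to the treatments stays open as an untested explanation. With an estimated correlation the adjusted p was 0.109, experiment 1 has no sham array, and RNA quality was not tested for this list.

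The NF-kB list rose with irradiation on top of TGFβ by a median of 0.25. Blood or endothelial cells would bring their own transcripts, but the median change of their markers was -0.0211, 0 of 13 were called higher, and the highest mean level among them was 5.90. In dishes of a cultured epithelial line this outcome was likely beforehand, so it lends the rise no support. The rise was not confined to 1 experiment, as the smaller of the medians was 0.2674 (experiment 2) against 0.428 in experiment 1, with 19 of 23 members above 0 in each. Its size did differ for some members. CXCL8, CCL20 and IL1A rose more in experiment 1, by differences that were called. IL1B, CXCL3 and PTGS2 had larger estimates in experiment 2, by differences that were not called. Cyclic loess gave a median of 0.26. A response to the irradiation itself and other differences between dishes stay open, as untested explanations.

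In the IR group, array IR 12 lay far from the others in BUB1B (8.858, nearest other 8.61) and MKI67 (9.019, nearest other 8.52), both G2 and mitosis genes. These are 2 of 432 groups of 4 arrays tested, 0.463%. Chance gives about 5% for 4 arrays of 1 kind, a rate that does not carry over to these groups, each of 2 arrays from each of 2 experiments that differ.

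Splits of the same arrays into other groups of the same sizes gave fewer genes. For TGFβ against sham 1 of 35 splits, the real one, reached 376 and the highest other gave 69. For IR against sham 1 of 35 reached 3 and the highest other gave 1, and for IR+TGFβ against sham 1 of 35 reached 1644 and the highest other gave 197. For IR+TGFβ against TGFβ 1 of 35 reached 435 and the highest other gave 2, and for IR+TGFβ against IR 1 of 35 reached 1225 and the highest other gave 6. Many of the 35 splits also mix the experiments, so they are not comparable with the real one. Only 10 splits of each comparison with sham and 18 of each of the other 2 spread the experiment 1 arrays as the real one does, too few for a share under 0.05. Among these the highest other gave 0, 1 and 0 genes for the comparisons with sham, in the order above, and 1 and 0 for the others. For IR against sham the margin is 3 genes against 1, and the count was 1 without IR 22 or sham 21 and 0 without the experiment term. For the interaction the real count was 0, which 100 of 100 random splits must reach, so they test nothing there; the highest gave 18.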

How the results depend on the processing

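The fits to experiment 1 alone and with the IR+TGFβ arrays of experiment 2 only were chosen after the data were seen; the other alternatives were planned. Counts are in the order TGFβ, IR and IR+TGFβ against sham, then IR+TGFβ against TGFβ and against IR, where the counts with all arrays were 376, 3, 1644, 435 and 1225. Under cyclic loess, median centring, the brighter genes and the mean of a gene's probe sets each of these counts stayed within 1.5 times.

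Without the experiment term the counts were 151, 0, 447, 0 and 405, and with the experiment as a random block 198, 1, 856, 9 and 753; differences between the experiments then enter the spread and, against sham, the changes too. The experiment 2 arrays alone gave 618 for TGFβ against sham, 18 for IR+TGFβ against TGFβ and 540 for IR+TGFβ against IR, and the experiment 1 arrays alone gave 680 and 698 for the last pair, with fewer arrays. With the IR+TGFβ arrays of experiment 2 only, that pair had 51 and 604 and the interaction 1. With only the compared groups in the fit the counts were 668 for TGFβ against sham, 1040 for IR+TGFβ against sham and 112 for IR+TGFβ against TGFβ. Against sham such a fit takes the change from the experiment 2 arrays alone, as all experiment 1 arrays are then of the treated group. Those arrays add only to the estimate of the spread. The cause of the other differences in count was not tested. The trend and robust options gave 10 genes for IR against sham and 1 for the interaction; the cause was not tested. A block for the 2-digit replicate number gave 57 for IR+TGFβ against TGFβ and 571 for IR+TGFβ against IR. Whether the numbers pair the arrays stays open. Of 12 pairs with the same number 7 correlated above 0.1, with a range of -0.329 to 0.622 over the 12. Of 15 arrays 4 correlated best with an array of their own number. Arrays of the same number are also of the same experiment, and these correlations still hold the difference between the experiments. They therefore cannot show or exclude such a pairing.

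A log2 change over 0.8 in addition left 85, 222, 47 and 127 genes (all but IR against sham), by its construction. The methods' rule for the comparisons with sham, taken as a two-sided equal-variance test with no experiment term, gave 37, 0 and 88, and 8, 0 and 35 after Benjamini-Hochberg adjustment. The methods' t-test alone gave 1197 and 508 for TGFβ and IR, and after adjustment 16, 0 and 113 for the comparisons with sham.

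Of the gene lists 12, 8, 11, 6 and 12 were called in the order above, and 6 for the interaction. With an estimated correlation these were 5, 2, 5, 2, 5 and 0, as that correlation widens the test. By fry IR against sham had 4 and the interaction 2, and without the experiment term IR against sham had 5; the cause was not tested. The correlation across genes of the TGFβ effects without and with irradiation was 0.4955 without the experiment term, and that of the IR effects turned to -0.1383, because all sham arrays are of experiment 2.

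Leaving out 1 array at a time gave 202 to 405, 1 to 9, 1018 to 1631, 96 to 489 and 796 to 1239 genes, and 0 to 1 for the interaction. The lists called ran from 10 to 13, 6 to 9, 9 to 11, 6 to 9 and 11 to 14, and 5 to 7 for the interaction. The correlations ran from 0.671 to 0.7525 and from 0.2925 to 0.4749.

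No named gene that was called changed direction. For the genes named by size the naming rule fixed this in advance without the experiment term and in experiment 2 alone. Over the settings tried 8029 calls of named genes stayed on their side of the threshold, 575 were lost and 70 gained. Of the losses 187 were over the arrays left out in turn, 112 without the experiment term, 78 with it as a random block, 47 with the replicate block, 47 with the IR+TGFβ arrays of experiment 2 only, 46 in experiment 2 alone and 27 with only the compared groups. The others were 14 with trend and robust, 11 in experiment 1 alone, 4 with the mean of probe sets, 1 with median centring and 1 without _x_at probe sets. Precision limits what can be seen: at a median standard error of 0.0953 against sham, simulated changes of 0.5 were recovered in 70% to 86% of genes for those contrasts. That simulation had an additive experiment effect, which does not hold for every gene here.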

Other observations

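The values in this part were looked for only after the difference between the experiments was seen. Experiment 2 differed from experiment 1 in 1014 genes within the IR arrays, 1946 within the TGFβ arrays and 492 within the IR+TGFβ arrays. The EGF receptor ligand and ERK feedback list was higher in experiment 2 by a median of 0.77 within IR (camera adjusted p = 1.05e-17), 1.21 within TGFβ (1.91e-16) and 0.21 within IR+TGFβ (0.00047). The S phase list was lower, by -0.31, -0.60 and -0.49 (adjusted p = 9.7e-07, 3.55e-13 and 1.31e-14), and the G2 and mitosis list by -0.74 within TGFβ (5.74e-19) and -0.38 within IR+TGFβ (1.27e-15), with -0.12 within IR not called (0.291). With an estimated correlation the adjusted p-values within IR, TGFβ and IR+TGFβ were 0.0465, 0.0516 and 0.335 for the ERK feedback list and 0.0949, 0.0253 and 0.0207 for the S phase list, and for the G2 and mitosis list 0.0207 within TGFβ and 0.0253 within IR+TGFβ. The NF-kB list was higher in experiment 2 by medians of 0.18, 0.35 and 0.47 within IR, TGFβ and IR+TGFβ (adjusted p = 0.0207 in each with an estimated correlation). The TGFβ/SMAD-induced list was higher by 0.18, 0.20 and 0.23 (0.032, 0.0253 and 0.0132). Within IR+TGFβ the actin list was higher by 0.21 and the p53 target list lower by -0.25 (0.0207 for each).

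The G2 and mitosis list also moved in opposite directions between TGFβ and IR arrays: it was higher with TGFβ by a median of 0.44 in experiment 1 and lower by -0.17 in experiment 2, a difference of -0.57 (camera adjusted p = 2.55e-33, and 0.00774 with an estimated correlation). In experiment 2 the lower median was not called with an estimated correlation (0.168). Its mean level was 9.61 to 9.71 on the 3 sham arrays, 9.23 on both TGFβ arrays of experiment 2, and 9.97 and 10.0 on those of experiment 1. Experiment 1 has no sham array, so its own TGFβ effect on dividing cells was not measured.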
